A study of Homo sapiens with 21 samples.

How the data were processed

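Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in MCF-7 cells (an established oestrogen receptor positive breast cancer line) and in human mesenchymal stem cells (MSC). RNA was sequenced from MCF-7 only; the labels describe rRNA-depleted total RNA. There were 9 MCF-7 and 6 MSC peak lists and 6 RNA count tables. Groups came from the cell type labels and, for RNA, from the library named in the description. The design text counts 3 ATAC-seq libraries per cell type, each with technical replicates, and the labels do not tie lists to libraries. P-values over lists therefore measure a spread that is partly technical and are too small; 3 libraries against 3 could not go below a p of 0.10. The design text describes the 3 tables of each RNA library as lanes, so RNA was treated as 1 library per group. The count headers instead number the 3 tables of a library as separate RNAs, and their spread, given below, argues against lanes alone; whether they are separate libraries or separate cultures is not settled.

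Peaks were called per list with MACS2 on hg19, per the submitters' processing notes, which also name SAMtools 1.6 and bedtools; whether reads were shifted for the transposase, and the aligner, are not given in the sources used here. Each peak carries a score, a fold enrichment (a ratio), and a −log10 p and −log10 q, all as the authors deposited them; for the comparisons of the report these values served only to rank or filter peaks within a list. In the closing section, −log10 p at a given fold enrichment was also compared between lists, as a check on read number. RNA values are raw counts per gene made with featureCounts 1.5.1 on a UCSC hg19 annotation with reverse-strand, paired counting and a mapping quality filter, per the file headers. The labels' protocol describes single-read sequencing by ligation on another instrument than the headers name, so the RNA platform is uncertain. Tags in file names and headers that resemble treatments or times are not explained by the labels and were not used for grouping.

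Peaks on the autosomes and X were kept. To compare lists of unlike length, each was reduced to its strongest 48795 peaks by −log10 p, the size of the smallest list. Gene positions came from the count tables (hg19, 1 outermost start per gene). Biotypes were matched by symbol for 95.74% of 26364 genes in a RefSeq table of GRCh38.p14, of which no coordinate was used; 18646 protein-coding genes had 1 location. A promoter peak lay within 1 kb of the gene start, and a gene locus was the gene body with 25 kb on either side. Regions were merged with bedtools 2.31.1 where peaks overlapped by at least 1 bp, and called in a type when at least 75% of its lists held a peak (7 of 9 MCF-7, 5 of 6 MSC). Values per list were compared with two-sided exact permutation tests over all 5005 splits of the lists, whose smallest p is 0.0002. Adjusted p-values are Benjamini-Hochberg values, over the 16980 loci with at least 1 peak on average in 1 type, or over 28 gene lists.

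RNA tables were summed per library and scaled by TMM (edgeR 4.0.16). Genes with at least 20 counts were given a fold with an exact conditional binomial 95% interval, and called different beyond counting error at a fold of at least 2 with a near bound of at least 1.5. These intervals cover counting error only. The tables of 1 library differed by more than that. The mean chi-square per degree of freedom was 11.4 in library 1 and 7.67 in library 2, and the median 3.63 and 2.98. Counting error alone, as between lanes of 1 library, gives a mean of 1. Adjusted p-values from edgeR's quasi-likelihood test over the 3 tables per library are given beside folds; taken as lanes, the tables compare these 2 libraries and not conditions, and if the tables are separate RNAs the p-values measure the spread between those. Log2 folds used a prior count of 0.5. A list's median was ranked among medians of 10000 random lists of the same size, matched on mean expression in 20 bins.

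The 30 gene lists, the tests and the rule for named genes were fixed before the data were examined. Of 388 list members 14 had no match, among them all mitochondrially encoded genes, so that list gave no value; the blood cell list had 1 measured gene in RNA, and no median was formed. The rule named members of the lists as examples; the 12 loci per direction with the largest difference among protein-coding genes with an adjusted p under 0.05 and no overlap of ranges, skipping overlapping loci; 10 promoters open in all 9 MCF-7 and no MSC list, by RNA count, and 10 open in all 6 MSC and no MCF-7 list, by mean percentile of peak strength; and the 12 largest RNA folds per direction with at least 100 counts. XIST and Y-linked genes were left out.

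The tests were tried on simulated data. For RNA, 200 of 15294 genes were changed 3-fold with counting error only, and the interval recovered 100.0% with 3 false calls. The real tables differed by more than counting error, so this number of false calls does not carry over to them. For edgeR the simulated tables also held the extra spread estimated from the real ones. It recovered 99% of 200 among 15280 genes with 2 false calls. For loci, 200 of 16980 genes were changed 3-fold in 4 simulations. With Poisson noise and a mean of at least 2 peaks the locus test recovered 0.0%, because only 35 genes reached the smallest p and 68 were needed. The other simulations were added after that outcome. With Poisson noise and a mean of at least 5 peaks it recovered 49.0%. With the variance seen between lists of 1 type (0.138 of the mean) it recovered 87.5% at a mean of at least 2 and 97.5% at a mean of at least 5. No simulation gave a false call. The locus test thus has little power where few loci change and peak numbers are noisy. The simulated lists were drawn independently, while the real ones are technical replicates of 3 libraries per cell type. Some real loci also varied far more between lists, such as BRIP1 with 37.2 ± 20.6 peaks in MCF-7. The recovered shares and the lack of false calls therefore do not carry over to the real lists.

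Alternatives covered all deposited peaks, a −log10 q of at least 5, other windows and overlap rules, other scalings and filters, DESeq2 1.42.0, and leaving out each list or table. Ranking by fold enrichment, leaving out MCF-7 lists 2 and 3 (whose peak names are built like those of the MSC lists), and leaving out genes near the MCF-7 loci were added after seeing the data. Motif content needs the hg19 sequence and was not analysed here.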

Results

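The data comprised 15 ATAC-seq peak lists, 9 from MCF-7 and 6 from MSC, and 6 RNA count tables from 2 MCF-7 libraries, RNA 1 and RNA 2. MCF-7 lists held 48795 to 205341 peaks and MSC lists 185706 to 255688; read depth per list is unknown. RNA tables held 25624074 to 34104149 counts for RNA 1 and 26773640 to 30637608 for RNA 2. The series title names regulatory variants as its subject; no variant was analysed here. The design implies a comparison of accessible chromatin between the cell types, its relation to MCF-7 RNA, and a comparison of the 2 RNA libraries.

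MSC lists were longer than MCF-7 lists. They held 228978 ± 27252 peaks (SD, n = 6) against 86366 ± 53929 (SD, n = 9; exact permutation p = 0.000599), and covered 87.2 ± 8.77 Mb against 38.0 ± 25.5 Mb (exact permutation p = 0.003). The longest MCF-7 lists, 2 and 3 (205341 and 145698 peaks), have peak names built like those of the MSC lists. List length may therefore reflect handling as well as cell type. At equal size, lists of 1 type shared more than lists of different types. The mean Jaccard index in base pairs was 0.575 within MCF-7, 0.714 within MSC and 0.233 between types, a difference of 0.383 (exact permutation p = 0.0002, the smallest possible over 15 lists).

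Of 117026 merged regions, 18669 were called in MCF-7 and held by no MSC list, 22374 were called in MSC and held by no MCF-7 list, and 15054 were called in both. Shared regions lay mostly at gene starts: 55.7% were within 1 kb of one, against 7.72% of MCF-7-only and 3.52% of MSC-only regions. The share of a list's peaks at gene starts was 25.0 ± 1.16% in MCF-7 (SD, n = 9) and 21.3 ± 0.516% in MSC (SD, n = 6; exact permutation p = 0.0002). These classes are relative to the strongest peaks. With all deposited peaks, 9205 regions were MCF-7-only, 72917 MSC-only and 28673 shared.

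Promoters of luminal epithelial genes were open in MCF-7 and mostly not among the strongest peaks of MSC. Of 20 such genes, 95 ± 2.5% had a promoter peak in MCF-7 (SD, n = 9) and 20.8 ± 8.01% in MSC (SD, n = 6). Relative to all protein-coding genes the difference was 69.4 percentage points (exact permutation, adjusted p = 0.000466). FOXA1, a pioneer factor of the oestrogen receptor, the epithelial cadherin CDH1, the adhesion molecule EPCAM and the keratin KRT19 had promoter peaks in 9 MCF-7 and 0 MSC lists. With all deposited peaks, 6 MSC lists held one at FOXA1 and EPCAM, 5 at CDH1 and 1 at KRT19. Promoters of AGR2 and CLDN7 had a peak in 0 MSC lists under either choice.

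Collagen and extracellular matrix genes showed the opposite. A promoter peak was present at 49.4 ± 3.91% of 20 genes in MCF-7 and 70.0 ± 3.16% in MSC, a difference of -25.4 points relative to all genes (exact permutation, adjusted p = 0.000466). COL6A3, SPARC and THBS2 had promoter peaks in 6 MSC and 0 MCF-7 lists, also with all peaks. Interferon-stimulated genes had 54.2 ± 5.41% in MCF-7 and 74.0 ± 10.8% in MSC, a difference of -24.6 points (exact permutation, adjusted p = 0.000466), with OAS2 and IFI44 open in 6 MSC and 0 MCF-7 lists. In this gene list IFIT2 (7 MCF-7 and 0 MSC lists) and RSAD2 (8 and 2) went the other way at equal size. The luminal, extracellular matrix and interferon gene lists kept their call and direction under all 5 alternatives tried, while 17 of the 20 called lists did not. The size of the difference varied, from 43.73 to 77.23 points for luminal and from -25.94 to -14.11 for interferon-stimulated genes. For extracellular matrix genes it ran from -33.6 to -8.99 points (exact permutation, highest adjusted p = 0.0373).

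The other called lists depended on a setting. Mesenchymal transcription factors and adhesion genes differed by -22.96 points, with VIM, an intermediate filament of mesenchymal cells, and TWIST2 open in 6 MSC and 0 MCF-7 lists, but by -2.53 (adjusted p = 0.434) with peaks ranked by fold enrichment. In the same list ZEB1 and SNAI1, repressors of epithelial genes, went the other way, with promoter peaks in 9 MCF-7 and 0 MSC lists at equal size and in 6 MSC lists with all peaks. Smooth muscle genes differed by -18.7, blood cell markers by -16.54, oestrogen-repressed genes by -16.47, YAP and TEAD targets by -9.81, heat shock genes by -7.28, cholesterol synthesis by -7.12, bone-forming genes by -6.47, cell cycle by -5.09 and ribosomal protein genes by -3.04 points. Hypoxia genes, p53 targets and the 9p21 genes each differed by -4.81 points only because the share over all genes moved; their own mean shares were equal in both types. The same shift over all genes made up most of 4 further differences, where the own share differed by -0.28 points for cell cycle, -1.67 for bone-forming, -2.31 for cholesterol synthesis and -2.47 for heat shock genes. The own share of ribosomal protein genes was 96.5% in MCF-7 and 94.7% in MSC, the other way round from its difference relative to all genes. Basal epithelial genes differed by 15.33, fat-forming genes by 13.94, endothelial markers by 12.65 and oestrogen-induced genes by 11.41 points. The 8 lists without a call were MSC surface markers at -7.33, replication-dependent histones at -3.70, cartilage at -3.22, housekeeping at -1.63, DNA replication at -1.10, unfolded protein response at 1.21, AP-1 factors at 1.86 and immediate early genes at 1.94 points.

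**Figure D1:**
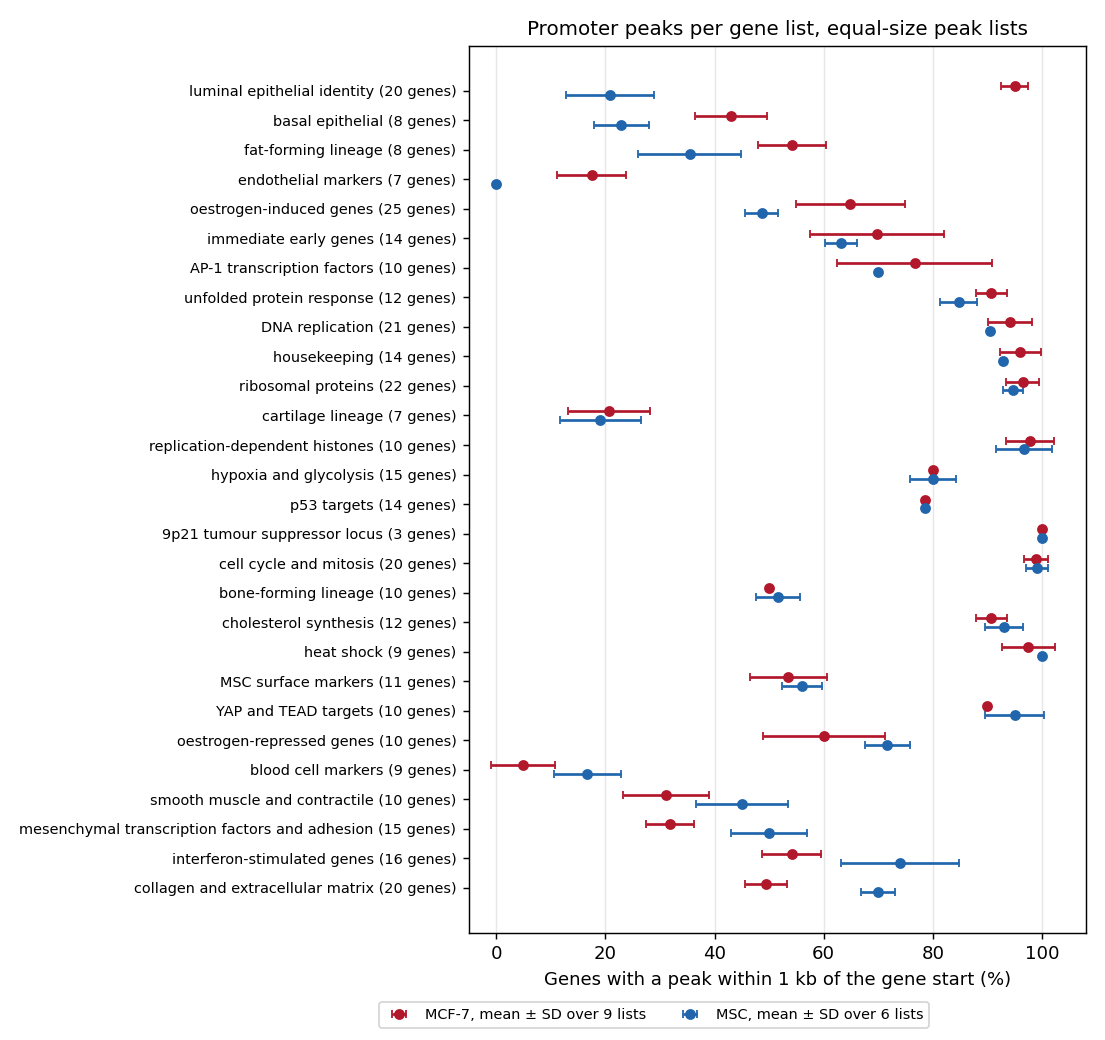
Percentage of each list's genes with a peak within 1 kb of the gene start, as mean ± SD over 9 MCF-7 and 6 MSC peak lists of equal size. Luminal epithelial genes stand at 95% in MCF-7 and 20.8% in MSC, and extracellular matrix genes at 49.4% and 70.0%.

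Across protein-coding genes, 735 promoters had a peak in all 9 MCF-7 and no MSC list, and 391 in all 6 MSC and no MCF-7 list. With all deposited peaks only 36 of the 735 and 244 of the 391 kept that status. The 10 MCF-7 promoters with most RNA were KRT19, PREX1, CDH1, SPTSSB, SPINT2, SULF2, EPHB4, BMP7, LY6E and ADAR. KRT19 (chromosome 17, 39679869 to 39684641, hg19) had 2314 CPM in RNA 1 and 4064 in RNA 2. Of these 10, PREX1 (a Rac exchange factor) and KRT19 had a peak in 1 MSC list when all peaks were used; BMP7 had one in 4, CDH1 in 5 and the other 6 genes in 6. The 10 strongest MSC promoters were SPAG16, ZNF132, ZNF471, FAM129B, TMEM71, TCTEX1D4, BTBD19, CRYAB, HSPB2 and CCDC89. CRYAB, a small heat shock protein, and its neighbour HSPB2 share 1 peak region at a mean percentile of 95.8 ± 1.27 (SD, n = 6), as do TCTEX1D4 and BTBD19. FAM129B had 389 CPM in RNA 1 without a peak at its annotated start in the MCF-7 lists of equal size; 2 MCF-7 lists held one with all peaks, as did 5 at TCTEX1D4, 4 at BTBD19, 3 at CCDC89 and 1 at TMEM71. With a window of 5 kb the types no longer differed at KRT19, PREX1 and FAM129B, and with 500 bp at CRYAB. With peaks ranked by fold enrichment, BMP7 and LY6E lost their call.

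Gene loci differed widely in peak number. Of 16980 loci, 4960 had more peaks in MCF-7 and 4726 more in MSC (exact permutation tests, adjusted p under the threshold). With peaks ranked by fold enrichment the counts were 6129 and 3704, so that the share higher in MCF-7 went from 51.2% to 62.3%. It was 62.9% with a −log10 q of at least 5, where peak numbers were scaled per 100000 peaks of each list. With the gene body only, the majority turned, with 2767 loci higher in MCF-7 and 3159 in MSC (46.7% in MCF-7). Among luminal genes 19 of 20 loci were higher in MCF-7 and 0 in MSC, adjusted over the list alone also 19 and 0. GATA3 had 4.44 ± 1.24 peaks in MCF-7 and 0.333 ± 0.516 in MSC. Of 20 extracellular matrix loci 13 were higher in MSC and 1 in MCF-7, adjusted over the list alone also 13 and 1. Of 15 mesenchymal loci 9 were higher in MSC and 3 in MCF-7, with the same numbers adjusted over the list alone; CDH11 had 0.556 ± 0.527 and 7.67 ± 0.516 peaks.

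The 12 loci with the largest excess in MSC were GPC6, NRG1, ADAM12, CDH13, ROR1, DGKI, CTIF, KIRREL3, SPOCK1, CACNA1C, FMN1 and FGGY. GPC6, a glypican (chromosome 13, 93879078 to 95060273), had 28.2 ± 2.14 peaks in MSC (SD, n = 6) and 3.11 ± 0.601 in MCF-7 (SD, n = 9; exact permutation, adjusted p = 0.000776). NRG1, a ligand of ERBB receptors, had 23.3 ± 1.97 and 2.78 ± 0.667, and ADAM12, a metalloprotease, 21.8 ± 0.408 and 2.67 ± 1.41. All 12 stayed past the threshold with either ranking of peaks.

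The 12 loci with the largest excess in MCF-7 were BRIP1, BCAS3, RIMS2, DOK5, USP32, ADAMTS9, VAV3, BMP7, NTNG1, KIAA1217, CADPS and FGF12. BRIP1, a DNA repair helicase (chromosome 17, 59756547 to 59940920), had 37.2 ± 20.6 peaks in MCF-7 and 1.5 ± 0.837 in MSC (exact permutation, adjusted p = 0.00298). Only RIMS2, VAV3, KIAA1217 and FGF12 stayed past the threshold when peaks were ranked by fold enrichment; BRIP1 then differed by 9.50 peaks (adjusted p = 0.209). RIMS2 (chromosome 8, 104512976 to 105266656) had 25.7 ± 12.2 and 0.333 ± 0.516 peaks, and VAV3, a Rho exchange factor (chromosome 1, 108113782 to 108507545), 21.4 ± 3.00 and 2.17 ± 0.408 (exact permutation, adjusted p = 0.000776 for both).

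**Figure D2:**
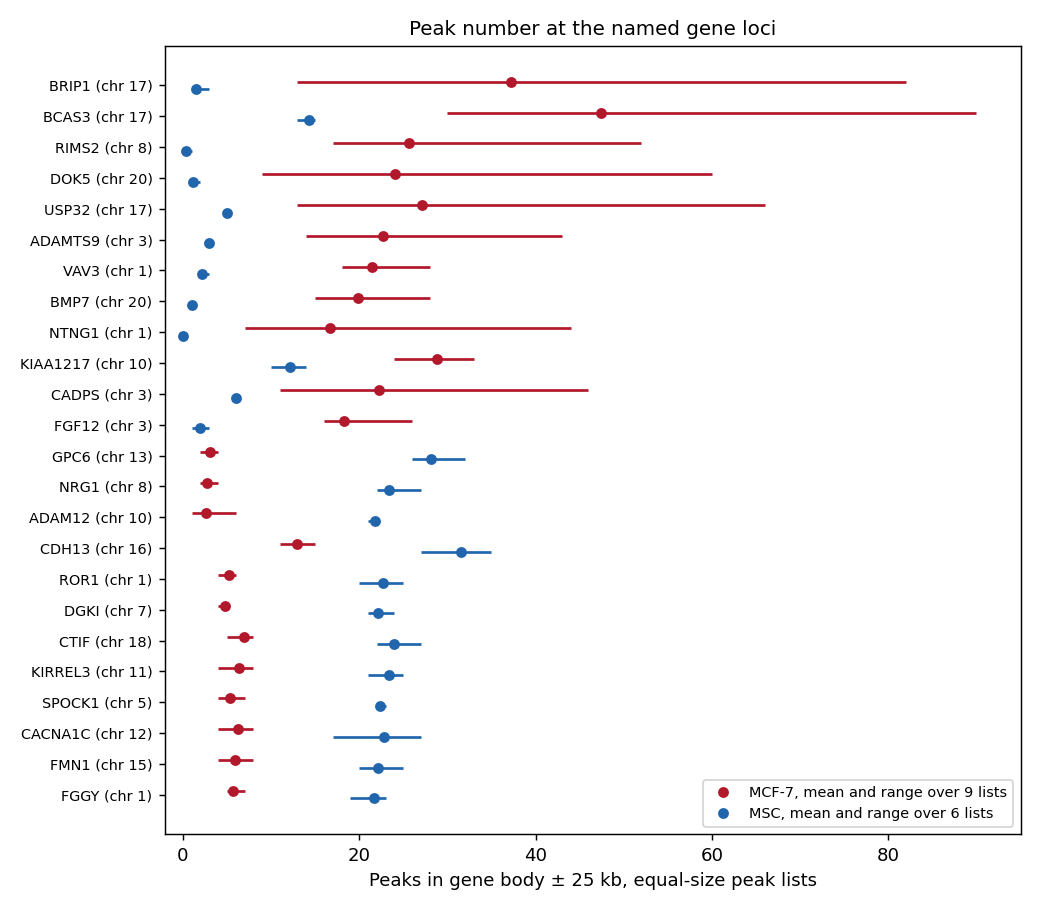
Number of peaks in the gene body with 25 kb on either side for the 24 named loci, as mean and range over 9 MCF-7 and 6 MSC lists of equal size. The rule for naming loci required ranges that do not overlap, so their separation here is no further evidence. BRIP1 has a mean of 37.2 peaks in MCF-7 and 1.5 in MSC, GPC6 3.11 and 28.2.

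In MCF-7, genes with a promoter peak had more RNA. Of 9589 genes with a peak in all 9 MCF-7 lists, 91.3% had at least 1 CPM (exact 95% interval 90.7 to 91.8%), against 19.5% (18.5 to 20.5%) of 6403 genes with a peak in 0 lists. Median levels were 32.6 CPM in RNA 1 and 31.3 in RNA 2 for the former and 0.012 CPM in both for the latter. Over the 9 lists and 2 libraries, the median was 29.0 to 31.0 CPM with a promoter peak and 0.023 to 0.036 without. Genes are not replicates, and no test was made.

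**Figure D3:**
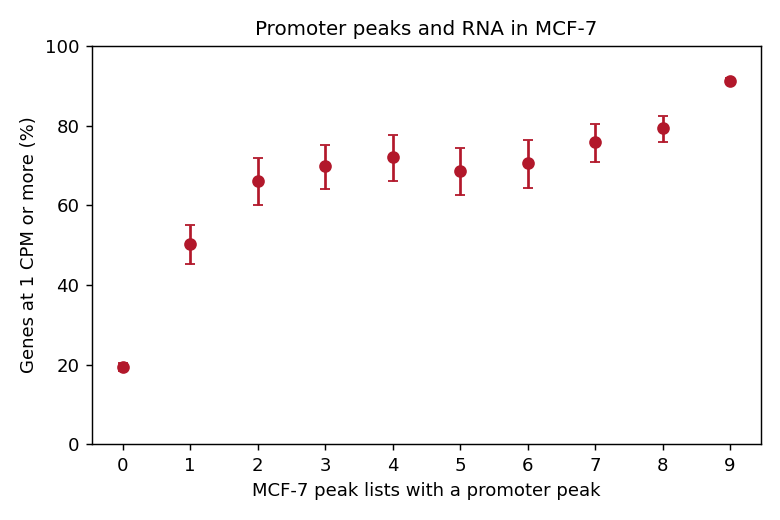
Percentage of protein-coding genes with at least 1 CPM (mean of both RNA libraries) by the number of MCF-7 peak lists with a promoter peak, with exact 95% binomial intervals. The share goes from 19.5% at 0 lists to 91.3% at 9 lists.

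The labels give no difference between libraries RNA 1 and RNA 2, yet they differed in oestrogen-responsive genes. Of 25 oestrogen-induced genes, 23 were higher in RNA 2 beyond counting error and 0 lower, with a list median 3.48-fold higher. PGR, the progesterone receptor, was 13.8-fold higher (95% counting interval 12.5 to 15.3), the receptor kinase RET 8.17-fold (7.92 to 8.43) and GREB1 6.20-fold (6.10 to 6.30). TFF1 was 2.81-fold higher (2.78 to 2.84). By edgeR over the tables, 24 of the 25 were higher over all genes tested and 25 adjusted over the list alone. Of 10 oestrogen-repressed genes, 7 were lower beyond counting error and 0 higher, with a median log2 fold of -1.38; all 10 were lower by edgeR, also adjusted over the list alone. IL1R1, an interleukin receptor, was 5.42-fold lower (4.82 to 6.11) and BMF, a pro-apoptotic factor, 4.23-fold lower (3.94 to 4.54). The receptor gene ESR1 itself was 2.59-fold lower in RNA 2 (2.54 to 2.63; edgeR adjusted p = 1.092e-09). By the design text there was 1 library per group, and these values then compare 2 libraries and not conditions. The count headers number the 3 tables of each library as separate RNAs, and the tables differed by more than counting error (median chi-square per degree of freedom 3.63 and 2.98), which lanes of 1 library would not give; whether they are separate libraries or cultures is uncertain.

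Among 15295 genes, 572 were higher and 380 lower in RNA 2 beyond counting error; 908 of these 952 also passed edgeR's test over the tables. The 12 largest increases were FGFBP2, CYP24A1, TFF2, MGAT3, SEMA3G, KIAA1644, TGM2, TUBA3E, BMPER, HCK, LOXL4 and VWF. TGM2, a transglutaminase, was 21.4-fold higher (18.3 to 25.3) and CYP24A1, the vitamin D hydroxylase, 34.7-fold (15.7 to 95.7). FGFBP2 had 3 counts in RNA 1 and 139 in RNA 2, a ratio of 49.5 (16.6 to 242.8). TUBA3E has near-identical paralogs, so its count is uncertain. The 12 largest decreases were NXPH1, PALMD, ST8SIA1, HCAR2, BLNK, CLIP4, TUBAL3, MUM1L1, GRHL3, B3GNT5, LMOD1 and VTCN1. GRHL3, an epithelial transcription factor, was 6.50-fold lower in RNA 2 (edgeR adjusted p = 3.218e-09) and NXPH1 12.8-fold lower (edgeR adjusted p = 3.601e-08).

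DNA replication genes were slightly higher in RNA 2, with a median log2 fold of 0.36 at percentile 100.0 of random lists; 0 of 21 passed the 2-fold limit, and 17 were higher by edgeR (18 adjusted over the list alone). Extracellular matrix genes had a median of 0.76 (percentile 100.0), with 6 of 18 higher, among them COL1A1 at 2.38-fold and SPARC at 2.58-fold. Their tables varied: COL1A2 had an edgeR adjusted p of 0.1455. Mesenchymal genes had a median of 1.04 (8 measured, 2 higher and 1 lower), bone-forming genes 0.75 (0.32 to 0.43 in 4 fits that left out 1 table), cartilage genes 0.64, AP-1 factors 0.45, fat-forming genes 0.44, hypoxia genes 0.31, unfolded protein response genes 0.26, endothelial markers 0.22, luminal genes 0.21 and heat shock genes 0.20. Cholesterol synthesis and immediate early genes were both at 0.10 (cholesterol synthesis 0.16 without replicate 2 of RNA 1), and housekeeping genes at 0.04. Below 0 were ribosomal protein genes at -0.02, nuclear retained RNAs at -0.05, basal epithelial genes at -0.07, MSC surface markers at -0.08, interferon-stimulated genes at -0.11, cell cycle genes at -0.15, p53 targets at -0.21, smooth muscle genes at -0.27, histone genes at -0.36, YAP and TEAD targets at -0.42 and the 9p21 genes at -0.82. With total count scaling the median over all genes went from -0.005 to -0.074, and every list median fell by the same amount. This was more than the SD of the list median between tables only for 8 lists. That SD was taken over medians from single tables and combined over both libraries. The 8 lists were bone-forming at 0.68, DNA replication 0.29, luminal 0.14, heat shock 0.13, cholesterol synthesis 0.03, housekeeping -0.03, ribosomal protein -0.09 and cell cycle genes -0.22. Heat shock genes were also at 0.15 and 0.14 without replicate 1 or 3 of RNA 2. Outside the central 95% of random lists on the high side were also mesenchymal genes at percentile 99.93, hypoxia at 99.73, AP-1 factors at 99.66, luminal at 99.56 and unfolded protein response genes at 99.03. Bone-forming genes stood at percentile 99.64 with all tables, but their medians in the 4 fits named lay inside the band of -0.49 to 0.46 found for random lists with all tables. On the low side were YAP and TEAD targets at percentile 0.07, cell cycle at 0.44, p53 targets at 0.75, histones at 1.14 and the 9p21 genes at 2.09. This SD between single tables was 1.11 for the 9p21 genes, more than the size of their median. It was also above the size of the median for fat-forming (0.51), endothelial (0.27) and interferon-stimulated genes (0.43), and for several lists with medians nearer 0. It was 0.81 for mesenchymal and 0.49 for extracellular matrix genes, so the medians of all these lists are uncertain. Apart from VIM and CDH11, no mesenchymal gene exceeded 1.303 CPM in either library. The mesenchymal median thus rests largely on genes near the floor. Of 20 cell cycle genes, 9 were lower and 0 higher by edgeR, with the same numbers adjusted over the list alone.

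**Figure D4:**
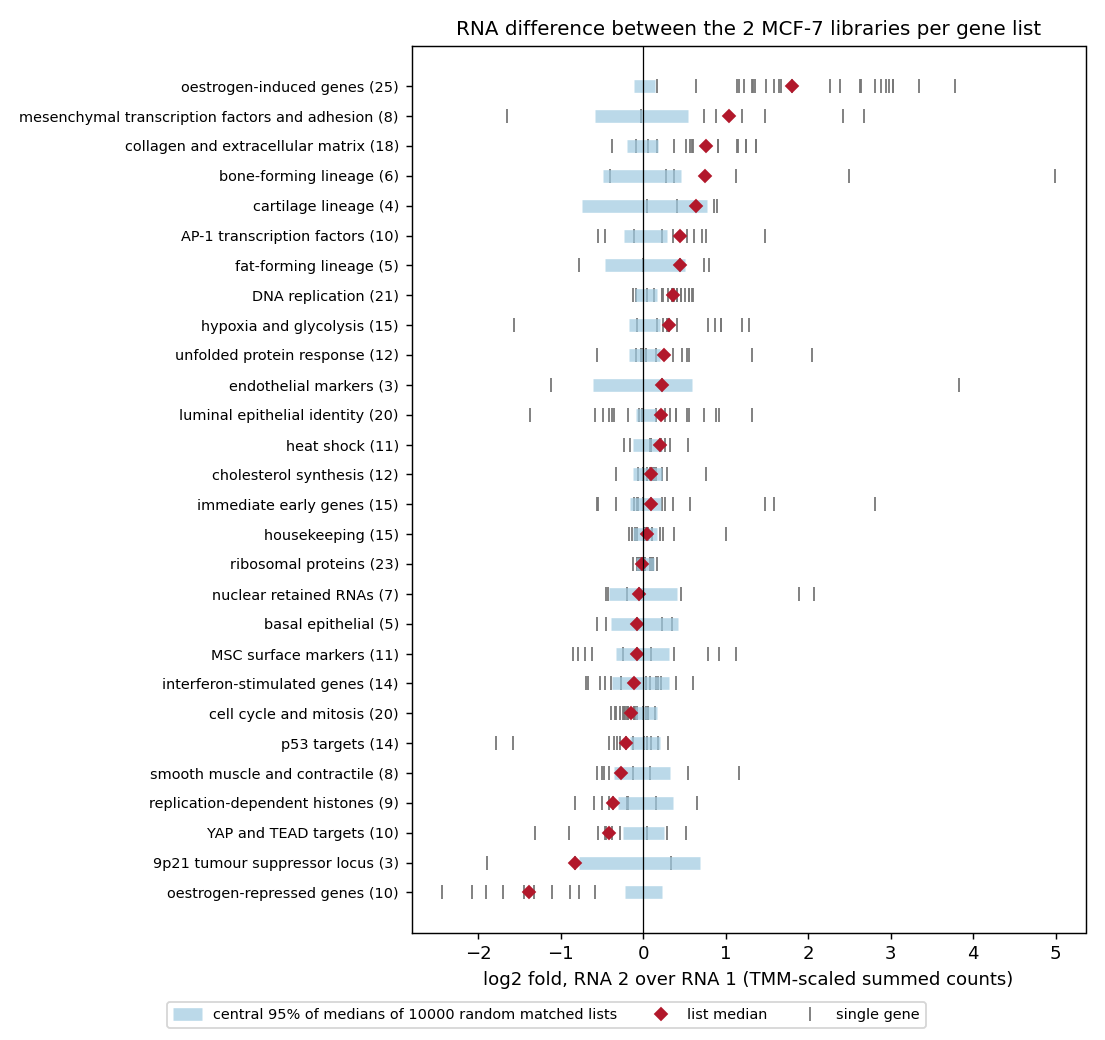
Log2 fold of RNA 2 over RNA 1 for each gene list, with single genes as ticks, list medians as diamonds and the central 95% of medians of 10000 random matched lists as bands; the number of measured genes is in brackets. Oestrogen-induced genes have a median of 1.80 and oestrogen-repressed genes of -1.38.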

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

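The 2 tests of the oestrogen pattern were chosen after its result was seen, as was the control near the MSC loci, and ranking by fold enrichment is an alternative added after seeing the data. Of 74 sets of list values examined, 15 single values stood far from the others of their type; chance gives about 1 in 20, or 3.7. Shares of short gene lists move in steps of 1 gene, so that 1 gene in 1 list is often enough, and no explanation was tested. In MSC list 5 the promoter share was 80% for oestrogen-repressed genes (the others 70%), 63.6% for MSC surface markers and 57.1% for immediate early genes. In MSC list 1 it was 12.5% for basal epithelial genes, 60% for bone-forming genes and 91.7% for the unfolded protein response. MSC list 4 had 95% for cell cycle genes, and MSC list 6 had 100.0% for cholesterol synthesis and 90.9% for ribosomal protein genes. MCF-7 list 8 had 100.0% and list 1 had 90% for luminal genes. MCF-7 list 5 had 20% for mesenchymal genes, list 9 had 83.3% for the unfolded protein response, list 4 had 83.3% for cholesterol synthesis and list 2 had 90.9% for ribosomal protein genes.

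The 12 loci with most extra MCF-7 peaks lie on few chromosomes. Of 265 genes 100 kb to 3 Mb from them, 55.85% were higher in MCF-7, against 29.2% of all tested loci; near the MSC loci the corresponding share was 31.8% against 27.8%. At equal fold enrichment, −log10 p near the loci was raised in MCF-7 lists only, by 0.3803 on the natural log scale relative to MSC, and by 0.3343 with the loci themselves left out; the mirror rise near the MSC loci was 0.0699, which argues against the choice of loci as the whole cause, though not as a part of it. With peaks ranked by fold enrichment, 4 of the 12 loci (RIMS2, VAV3, KIAA1217 and FGF12) stayed past the threshold. The loss of 8 may follow in part from their having been chosen by p, but this was not tested. All 12 MSC loci, chosen in the same way, stayed past it. Extra DNA copies, which would raise read number and p together, may account for these values, but copy number was not measured.

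MCF-7 lists range from 48795 to 205341 peaks. At a fold enrichment of 4.5 to 5.5, the lowest median −log10 p of lists 1 to 3 lay 0.584 above the highest of lists 4 to 9, a small margin (15.9 against 15.3), in the direction that deeper sequencing would give. The lowest share of a short list's peaks that overlapped the longest list was 94.28%, which argues against different open regions in the short lists. Length and p did not run in step, since list 3 (145698 peaks) had 27.4 and the longest, list 2, 25.0, while list 9 (50226) had 15.3, list 5 (69545) 14.5, list 8 (67735) 13.5 and list 7 (56002) 11.5. Depth may thus account for the gap between the 2 sets of lists but not for the order within them. Lists 2 and 3, the longest and highest in −log10 p, also have peak names built like those of the MSC lists. A difference in handling that goes with these names was not tested and cannot be told apart from depth. Read numbers are not known, and no biological explanation was tested.

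Oestrogen-induced genes were higher and oestrogen-repressed genes lower in RNA 2. The difference of the 2 list medians was 3.182 on the log2 scale, which no scaling changes, and at least 3.104 whichever table was left out. Both argue against scaling or 1 table as the cause. Medians were 0.04 for housekeeping and -0.02 for ribosomal protein genes (0 of 23 past the limit). TMM scaling sets most genes near no change, so these medians cannot tell whether genes of all kinds shared a difference. A difference in oestrogen exposure may explain the pattern; header tags of RNA 2, which the labels do not explain, resemble an oestradiol treatment, but this was not tested. Each library is 1 group, so other differences between the cultures cannot be separated. The spread of the 3 tables per library argues against lanes alone but leaves libraries or cultures open. Its mean chi-square per degree of freedom was 11.4 and 7.67, where lanes give 1.

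For gene loci, 1 of 100 drawn splits of the 15 lists, the real one, gave as many changed genes (9686), and the highest of the others gave 0. The other splits mixed the cell types, and a locus that separates the types can hardly reach the smallest p in such a split. The 0 therefore adds little, and the comparison takes the lists as independent. Chance is not excluded at the level of the 3 libraries per cell type, to which the labels do not tie the lists. For the RNA tables only 10 splits exist, too few for a share under 0.05; the real split gave 934 genes and the highest other 0.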

How the results depend on the processing

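Ranking by fold enrichment was chosen after seeing the data, as was leaving out MCF-7 lists 2 and 3. The similarity of lists and the promoter share kept direction and call under every alternative run for them. The counts of RNA genes and both oestrogen medians stayed within 1.5 times or 1 SD of their main value. Leaving out 1 list gave 18732 to 20364 MCF-7-only, 22434 to 23816 MSC-only and 15103 to 15404 shared regions, and 4566 to 4984 loci higher in MCF-7 and 4402 to 4672 in MSC; leaving out 1 table gave 487 to 625 genes higher and 349 to 398 lower in RNA 2, and medians of 1.767 to 1.882 and -1.419 to -1.306. All 24 RNA genes kept their call.

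MCF-7-only, MSC-only and shared regions numbered 9205, 72917 and 28673 with all peaks, and 8688, 68730 and 25762 at a −log10 q of at least 5, since MSC lists are longer; called in all lists, MCF-7-only fell to 11729. With the gene body only, 2767 loci were higher in MCF-7 and 3159 in MSC, which turned the majority. Gene lists higher in MCF-7 and MSC numbered 5 and 15, but 11 and 8 with all peaks and 8 and 4 ranked by fold enrichment; the cause was not tested. The share of genes at 1 CPM was 15.39% (0 lists) and 90.66% (9 lists) with all peaks, and 21.17% and 91.99% within 500 bp.

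List numbers did not pair the samples: same-numbered lists correlated at -0.07 to 0.051, and 0 of 6 correlated best with its own number. With the replicate block the difference was -128423.33 peaks and -42.93 Mb (exact sign-flip p = 0.0625 for both), the promoter share 3.117 points (exact p = 0.0312), and 0 and 0 loci passed, because 6 pairs cannot give a p below 0.03125, which 6474 loci reached unadjusted; the 24 named loci lost their call for that reason.

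Directions turned for these lists (points, MCF-7 minus MSC). With all peaks: fat-forming -1.27, YAP and TEAD 6.51, endothelial -2.06, 9p21 15.4, housekeeping 13.81, cell cycle 14.85, DNA replication 13.28, hypoxia 1.7, cholesterol 6.14, p53 2.7, heat shock 14.17, ribosomal 13.89, immediate early -2.46 and histones 14.29. All peaks raise the MSC share over all genes from 54.3% to 79.2%. Lists at 90.5 to 100% in MSC at equal size cannot follow such a rise. They are 9p21, heat shock, cell cycle, histones, YAP and TEAD, ribosomal, cholesterol, housekeeping and DNA replication. For the other lists the cause was not tested. Ranked by fold enrichment: MSC surface markers 0.07, bone-forming 2.84, YAP and TEAD 24.51, 9p21 0.07, housekeeping 6.81, hypoxia 7.84, heat shock 3.77, ribosomal 1.83 and histones 20.07. Within 5 kb: basal epithelial -22.18, cartilage 8.67, unfolded protein response -2.05 and p53 1.13. Within 500 bp: housekeeping 5.61, AP-1 -2.49 and immediate early -8.28. Without MCF-7 lists 2 and 3: AP-1 -1.81, DNA replication 0.1 and immediate early -2.45. The cause of these 4 groups was not tested. Motif alternatives were not run, for lack of the genome sequence.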

Other observations

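A stretch of chromosome 9 (hg19, 21837027 to 21993939, 156.9 kb) that covers most of CDKN2A, a cell cycle inhibitor gene, and the end of MTAP had a peak in 0 of the 9 MCF-7 lists with all deposited peaks, and 9 to 23 peaks in each of the 6 MSC lists. It was looked at because of the 9p21 gene list, and all genes here were chosen after their values were seen. It ranked 329 of 243300 such gaps by the smallest MSC peak number, and 8 longer gaps, the first at FAT3 on chromosome 11 with 28 to 36 MSC peaks, ranked at the top. CDKN2A had 59 counts in RNA 1 and 31 in RNA 2, MTAP 300 and 355, and CDKN2B 1327 and 335. The CDKN2A, MTAP and CDKN2B starts had a promoter peak in all 9 MCF-7 lists. No explanation was tested.

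KDR, a vascular growth factor receptor, and ADIPOQ, the adiponectin gene, had promoter peaks in 9 MCF-7 and 0 MSC lists at equal size, with 0.047 CPM or less in both RNA libraries; with all peaks, 6 MSC lists held one at KDR and 2 at ADIPOQ. VWF, an endothelial gene, was 14.3-fold higher in RNA 2 (95% counting interval 11.9 to 17.2) and had a promoter peak in 0 lists of either type. GREB1 had 1192 CPM in RNA 2 and a peak at its outermost annotated start in 0 MCF-7 lists, while its locus held 10.2 ± 1.48 peaks in MCF-7 (SD, n = 9) and 1.00 in MSC.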
